A study of Mus musculus with 17 samples.

How the data were processed

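Single-cell RNA was measured by Drop-seq, a droplet method that marks each captured transcript with a cell barcode and a unique molecular identifier (UMI), in the hypothalamus of 5 normally fed mice and 3 mice deprived of food for 24 hours. Per the labels' protocols, the tissue was dissected and dissociated into single cells, polyA RNA was captured, and the mice were B6D2F1 hybrids. The labels place 17 libraries in 5 batches. Batch 0 holds normal replicates 1 and 2, batch 1 normal replicate 3 and food-deprived replicate 1, batch 2 normal replicate 4 and food-deprived replicate 2, batch 3 normal replicate 5, and batch 4 food-deprived replicate 3. The replicate is the mouse, and all libraries of a mouse were summed.

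The deposited table of each library holds raw UMI counts per gene and cell barcode, whole numbers with no normalization by the authors. The submitters' processing notes give the genome build as mm9. The aligner and the counting tool are not given in the sources used here. A further deposited table holds raw UMI counts of the annotated cells of all libraries together, and the authors deposited 1 cluster name per cell, a categorical value with no unit, whose file and column names refer to an SVM. The library tables hold 23284 genes and 18300 barcodes. Of 14437 annotated cells, 14276 were joined to a library by batch, feeding state and barcode, and in all of these the counts of every gene equal those of the merged table. The other 161 cells share their barcode with another library of the same batch and state and were left out. The names comprise 46 clusters, 34 of them neuronal (18 GABA, 15 Glu and 1 Hista), and an unnamed remainder of 2309 cells, zothers. Clusters that share a stem were merged into a broad class: Astro, Ependy, Epith, IMO, MO, Macro, Micro, OPC, POPC, SCO, Tany, GABA, Glu and Hista. The abbreviations are those of the deposited names. The marker levels in the report show that MO carries genes of myelinating oligodendrocytes, IMO of newly formed oligodendrocytes, OPC of oligodendrocyte precursors, Tany of tanycytes and Epith of endothelial cells.

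The cells used hold 46904254 UMIs. Totals per mouse ranged from 290861 UMIs in 129 cells (normal replicate 1) to 12570644 UMIs in 3639 cells (food-deprived replicate 1), and the median cell of a mouse held 1444 to 2389 UMIs. Precision is set by the number of mice and by these totals. In the batch 0 mice most classes fell under the cell minimum given next.

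Raw UMI counts were summed per mouse and class, and mice with at least 20 cells of a class entered its test if at least 2 per group remained. This gave 11 tested classes. All neurons, the sum of GABA, Glu and Hista, is among them and shares its cells with GABA and Glu. MO used all 8 mice. All neurons, GABA and OPC used normal replicates 2 to 5 and the 3 food-deprived mice. Glu, Astro, Tany, Ependy and Epith used normal replicates 3 to 5 and the same 3. IMO and Micro used normal replicates 3 to 5 and food-deprived replicates 1 and 2. Food-deprived was compared with normal by the two-sided quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM factors and filterByExpr, a separate fit per class, and Benjamini-Hochberg adjustment within the class at 0.05. Values of tested genes in a class are CPM, edgeR's counts scaled to TMM-adjusted library totals, means ± SD over mice unless stated otherwise. CPM of libraries, marker sets, clusters and barcodes without a cluster name, of genes compared across classes and of Plin4 in neurons are scaled to plain totals. Fold changes are log2 of food-deprived over normal with the standard error (SE) implied by the F statistic. The sum of all annotated cells was tested likewise. The difference between the Glu and GABA responses was tested as a class by status term with the mouse as block, over 6 mice. Neuronal clusters used a minimum of 10 cells, and the neuronal cluster with the highest Agrp level in the normal mice, GABA15, a minimum of 5.

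Gene lists were tested with camera (limma 3.58.1) with its preset correlation of 0.01 in each class with at least 5 members past the filter, with Benjamini-Hochberg adjustment over the 209 list and class pairs. The lists were orexigenic peptides, anorexigenic peptides, feeding peptides, hypothalamic peptides, transmitter genes, peptide processing, immediate early genes, glucocorticoid-induced genes, FoxO and low-insulin genes, fatty acid oxidation and ketone genes, cholesterol synthesis, fatty acid synthesis, glycolysis, oxidative phosphorylation, mitochondrial-encoded transcripts, thyroid hormone handling, circadian clock, unfolded protein response, heat shock, interferon-induced, microglial activation, myelin and cytosolic ribosomal protein genes, and genes of blood, mural and fibroblast, pituitary, choroid plexus and extrahypothalamic neuron types and of sex. The score of a list in a mouse is the mean log2 CPM of its members. Scores and cell class shares were compared between groups by two-sided exact permutation tests over all splits of the mice.

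The classes, tests, lists, markers and the rule for naming genes were fixed before the data were examined. The rule names called genes, up to 4 members with the smallest p of each list past the threshold in a class, 13 fixed genes in all neurons, the feeding peptide list in GABA15, the 10 genes with the smallest p for the Glu and GABA difference, and the highest transmitter and peptide genes of each cluster. Genes named for their value with batch as block were chosen after these values were seen.

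Alternatives fixed at the same time were RLE size factors, the DESeq2 1.42.0 Wald test, no filter beyond a total above 0, batch as block, batches 1 and 2 alone with batch as block, leaving out the batch 0 mice, thinned counts, leaving out doublets called by Scrublet (scanpy 1.11.5), a minimum of 50 cells (20 in neuronal clusters and 10 in GABA15), adjustment over all classes together, neurons chosen by Agrp UMIs, camera with an estimated correlation, fry, other denominators, log2 and deeper cells for shares, and leaving out each mouse. With batch as block, 8 mice in 5 batches leave 2 residual degrees of freedom, and only batches 1 and 2 inform the comparison. Classes tested on fewer mice than MO leave fewer, and the spread behind a blocked p is largely pooled over genes. Chosen after seeing the data were the alternatives that use the 2 types of library described in the report, the block with RLE factors or DESeq2, the lists over batches 1 and 2 or without batch 0, the sum without unnamed cells, and leaving out neurons with at least 1% of UMIs from the myelin list.

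The tests were run on simulated data with the dispersions and totals of each class and 200 changed genes. These were drawn from genes at or above the median CPM of the class, so recovery of lower genes was not measured. At 4-fold, edgeR recovered 100% of changed genes in MO and OPC, 99% in all neurons, GABA and Glu, 98% in Ependy and Epith, 97% in Tany, 95% in the sum of all cells, 91% in IMO, 88% in Astro and 72% in Micro. At 2-fold it recovered 72% in MO, 70% in OPC, 56% in all neurons, 46% in GABA and in Glu, 35% in IMO, 33% in the sum, 29% in Epith, 27% in Ependy, 23% in Tany, 14% in Micro and 12% in Astro. False calls numbered 2 to 23 per class, and 0 to 6 where no gene was changed. With batch as block, 4-fold recovery was 86% in MO, 98% in OPC, 97% in all neurons and 88% in Tany, and 2-fold recovery 5%, 34%, 26% and 16%, with 7, 5, 19 and 14 false calls. False calls with the block were higher in GABA (45), Glu (33) and Epith (26), numbered 22 in the sum, and were 1 to 11 in the other classes. No batch effect was simulated, and the run with no changed gene did not use the block. These counts therefore do not measure how often the block gives false calls in the real data. The class by status term recovered 82% at 4-fold and 9% at 2-fold with 5 false calls. Camera was simulated in MO alone with a log2 shift of 0.5, and passed 5 of 5 shifted lists and 0 of 15 unshifted ones. Genes were drawn independently there, so this cannot show how often correlated genes give false list calls.

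Macro, POPC, SCO and Hista had too few cells per mouse to test. Barcodes without a cluster name were not used in any comparison.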

Results

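The series profiles single cells of the mouse hypothalamus in 5 normally fed and 3 food-deprived mice. The values below describe which peptide and transmitter genes marked the deposited clusters, and then how the classes compared between the groups.

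The leading peptide gene varied between the deposited neuronal clusters, and Gal, Sst and Cartpt each led several of them. Levels are over the mice with at least 5 cells of a cluster. GABA15 held Npy at 12870 ± 3363 CPM (SD, n = 5 mice) and Agrp at 5701 ± 2168 CPM. Glu14 held Avp at 81690 ± 37740 CPM and Oxt at 22620 ± 22160 CPM (n = 5), so that Oxt varied between mice by nearly its mean. Glu11 carried Tac2 at 10380 ± 2325 CPM and Kiss1 at 4033 ± 1817 CPM (n = 3), and GABA11 carried Gal at 6708 ± 1342 CPM with Ghrh at 3850 ± 1426 CPM (n = 3). Sst reached 9044 ± 2024 CPM in GABA14 (n = 5), Vip 11430 ± 7515 CPM in GABA9 (n = 6), and Avp 11940 ± 5192 CPM in GABA8 (n = 7), the largest GABA cluster tested below. GABA17 had Th at 2129 ± 607 CPM, above its Gad2 level of 709.6 ± 316 CPM, and Cartpt at 6577 ± 1823 CPM (n = 5). Gal was also the leading peptide of GABA13 (7475 ± 3853 CPM, n = 6), beside Kiss1 at 1340 ± 1050 CPM. Cartpt led in Glu5 at 3450 ± 692 CPM (n = 6). In Glu13, where 2 mice had enough cells, Pomc stood at 19220 and 39840 CPM, and in Glu12 Hcrt stood at 6921 and 47760 CPM with Npvf at 3864 and 11320 CPM. In Glu15 and Hista 1 mouse had enough cells, with Sst at 30090 CPM and Hdc at 3567 CPM. In Glu9, named for glutamate, Gad2 averaged 746 CPM and Slc17a6 377 CPM over 2 mice.

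**Figure D1:**
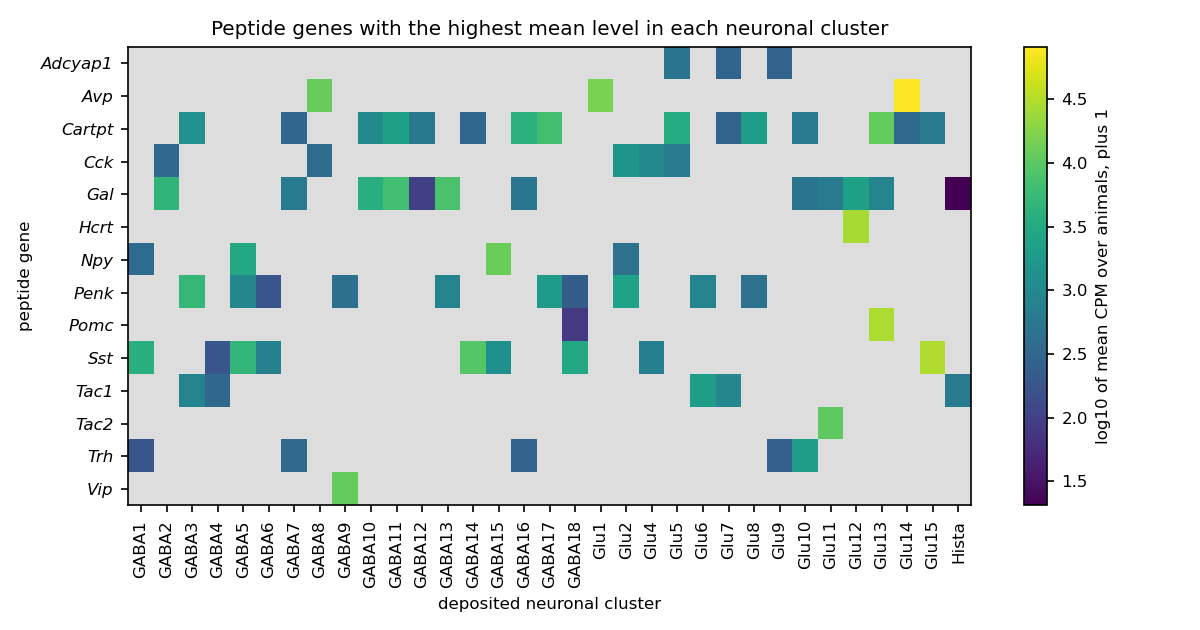
Rows are the peptide genes that lead at least 1 deposited neuronal cluster, and other peptide genes have no row. Colour gives the mean level over mice, as log10 of CPM plus 1, of a gene among the 3 leading peptide genes of a cluster. Grey marks a gene that is not among these 3, and clusters with too few cells in each mouse are not drawn. Avp in Glu14 is the highest level, at 81690 CPM.

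Marker sets fixed beforehand for the glial, vascular and transmitter classes were highest in the class whose name they match. The set for neurons as a whole was highest in Hista (8965 CPM, in 1 mouse with enough cells) and then in Glu (4993 ± 923 CPM, n = 8). The set of 7 myelinating oligodendrocyte genes reached 113800 ± 11550 CPM in MO and 38640 ± 8016 CPM in IMO (n = 8 each). Newly formed oligodendrocyte genes reached 9377 ± 498 CPM in IMO, and precursor genes 4165 ± 557 CPM in OPC. Astrocyte genes stood at 16480 ± 1647 CPM in Astro, tanycyte genes at 1906 ± 393 CPM in Tany, ependymal genes at 14670 ± 1519 CPM in Ependy and endothelial genes at 10380 ± 1237 CPM in Epith (n = 8 each). Microglial genes stood at 18820 ± 3012 CPM in Micro (n = 6) and macrophage genes at 8571 ± 3041 CPM in Macro (n = 5). Glutamatergic genes stood at 664 ± 98.7 CPM in Glu and GABAergic genes at 1734 ± 458 CPM in GABA. Astro also carried the myelin set at 8175 ± 7279 CPM, an SD close to the mean, and Ependy the histaminergic set at 760.4 ± 104 CPM. The pars tuberalis set was highest in Glu (1320 ± 279 CPM).

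Gapdh, Ppia and many ribosomal protein genes split the libraries, and not along the feeding groups. In 8 libraries Gapdh stood at 151 to 811 CPM and ribosomal protein genes took 2.86% to 5.45% of UMIs. In the other 9, Gapdh stood at 4.36 to 8.53 CPM and these genes took 1.9% to 2.32%. These are called retained and depleted libraries below, and values from depleted libraries alone also restrict the mice to batches 1 and 2 and use batch as block. Normal replicates 1, 2 and 5 and food-deprived replicate 3 have retained libraries only, normal replicate 3 depleted ones only, and the other 3 mice both. Within food-deprived replicates 1 and 2, which have both, 82 genes were at least 2 times higher in the retained libraries. Of the 77 of these with at least 20 CPM, 51 (66.2%) have a pseudogene named after them in the reference annotation, against 162 of 7740 other genes (2.09%; Fisher's exact test, two-sided, odds ratio 91.8, p = 3.7e-63, genes not being independent samples), and 40 are ribosomal protein genes.

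**Figure D2:**
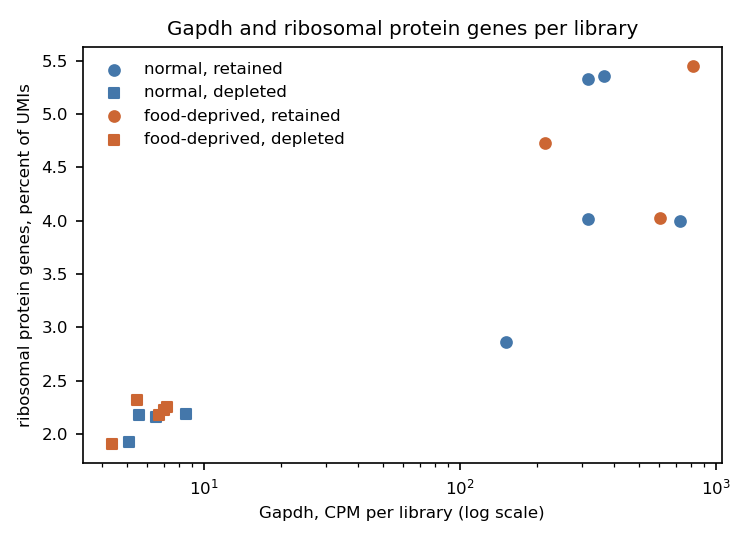
Each point is a library, with Gapdh in CPM on a log axis and the share of UMIs from ribosomal protein genes in percent. The 9 depleted libraries lie at 8.53 CPM of Gapdh or less and the 8 retained ones above 150 CPM, with both feeding groups in each set.

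Feeding peptides in neurons were compared first. Agrp averaged 1239 ± 2140 CPM in all neurons of 4 normal mice and 444.2 ± 261 CPM in 3 food-deprived mice (log2 -1.43 ± 1.13 SE), and Npy 2709 ± 3920 and 1188 ± 696 CPM (-1.17 ± 0.89). The normal mean of both rests on normal replicate 2, with 4448 CPM of Agrp and 8578 CPM of Npy, of whose 41 neurons 15 are GABA15 cells. Pomc averaged 288.6 ± 459 and 831.2 ± 890 CPM (1.46 ± 1.05), with food-deprived replicate 3 highest at 1850 CPM. Avp stood at 2851 ± 1085 and 4220 ± 793 CPM (0.56 ± 0.25), Gal at 729.6 ± 303 and 1056 ± 262 CPM (0.51 ± 0.32), and Cartpt at 1163 ± 549 and 1186 ± 462 CPM (0.03 ± 0.36). Sst, Trh, Crh, Vgf and Oxt had log2 ratios of 0.42, -0.30, -0.88, -0.62 and -1.13. Hcrt (4.50 ± 1.33) and Pmch (-2.22 ± 0.94) had large ratios that 1 mouse each carries, food-deprived replicate 2 with 2278 CPM of Hcrt and normal replicate 3 with 253.5 CPM of Pmch. The adjusted p of each of the 13 genes in edgeR is 1. Under batch as block Pomc was higher (2.58 ± 0.27 SE, adjusted p = 0.00223) and Agrp was not called (0.99 ± 0.24, adjusted p = 0.360). In depleted libraries alone Oxt, at 3.24, was called higher in the food-deprived mice (adjusted p = 4.37e-05), the opposite of its sign over all libraries, on the neurons of batches 1 and 2. Over all libraries these batches went opposite ways for Oxt. Normal replicate 3 had 58.9 CPM and food-deprived replicate 1 311.1 CPM, while normal replicate 4 had 3071 CPM and food-deprived replicate 2 365.9 CPM.

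No gene passed the threshold in any of the 11 classes with status as the only term. The smallest adjusted p in OPC was 0.248 (Hspa5) and in MO 0.286 (Gabrr2). Genes at an unadjusted p under 0.05 in edgeR numbered 232 in all neurons, 173 in GABA, 320 in Glu, 315 in MO, 150 in IMO, 291 in OPC, 183 in Astro, 182 in Tany, 237 in Ependy, 262 in Epith and 132 in Micro. DESeq2 called 1 gene, in MO, and 0 in the other 10 classes. In edgeR, leaving out normal replicate 3 gave 12 calls in Micro, food-deprived replicate 1 gave 3 in IMO and 1 in MO, and food-deprived replicate 2 gave 3 in IMO and 1 in Tany. IMO and Micro have 2 food-deprived mice, so leaving 1 of them out leaves a lone mouse that is assumed to vary like the normal ones, here and for the gene lists. A block for batch gave 53 calls, 16 in MO, 18 in OPC, 8 in all neurons, 7 in Tany, 3 in Glu and 1 in IMO. Pomc and Tac2 are counted both in all neurons and in Glu, which share cells. The genes named next were chosen after these values were seen.

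In MO, Plin4, which encodes a lipid droplet coat protein, stood at 33.9 ± 29.8 CPM in the normal mice (n = 5) and 138.5 ± 96.8 CPM in the food-deprived mice (n = 3). With batch as block, which only the mice of batches 1 and 2 inform, it rose (log2 2.13 ± 0.22 SE, adjusted p = 0.000491). The triglyceride lipase gene Pnpla2 (1.17 ± 0.21, adjusted p = 0.0294) and the protease gene Htra1 (1.34 ± 0.17, adjusted p = 0.00323) rose under the same fit. Elovl6, an elongase of fatty acid synthesis, fell by 0.95 on the log2 scale (adjusted p = 0.0291), and Micall1 by 1.00 (adjusted p = 0.0294). Each of these 5 genes lay on the same side within both shared batches and kept its call in depleted libraries alone, with adjusted p from 3.13e-05 to 0.00936. Without the block the values were 2.38, 1.32, 1.15, -0.79 and -0.92, with adjusted p from 0.338 to 0.79. In retained libraries alone, tested without the block, 0 genes passed in MO. Plin4, Htra1, Elovl6 and Micall1 stood there at 2.48, 1.17, -0.76 and -0.93, and Pnpla2 was under the filter. The other calls were Phyhd1, Pomc, Gabrr2, Scrg1, Itgad, Ogdhl, Gm15417 and Gstp1, higher, and Eml1, lower, of which Pomc and Gstp1 lost their call in depleted libraries alone (adjusted p of 0.416 and 0.114). Phyhd1 was highest of all mice in normal replicate 2, at 74.2 CPM, and 0 CPM in food-deprived replicate 3. Ppia (1.35) and Gapdh (1.79) were called as well, but in depleted libraries alone they stood at 0.39 and -0.14 with adjusted p of 0.568 and 0.976. Plin4 was near the floor of detection in neurons, at 1.3 and 1.2 CPM in the groups.

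**Figure D3:**
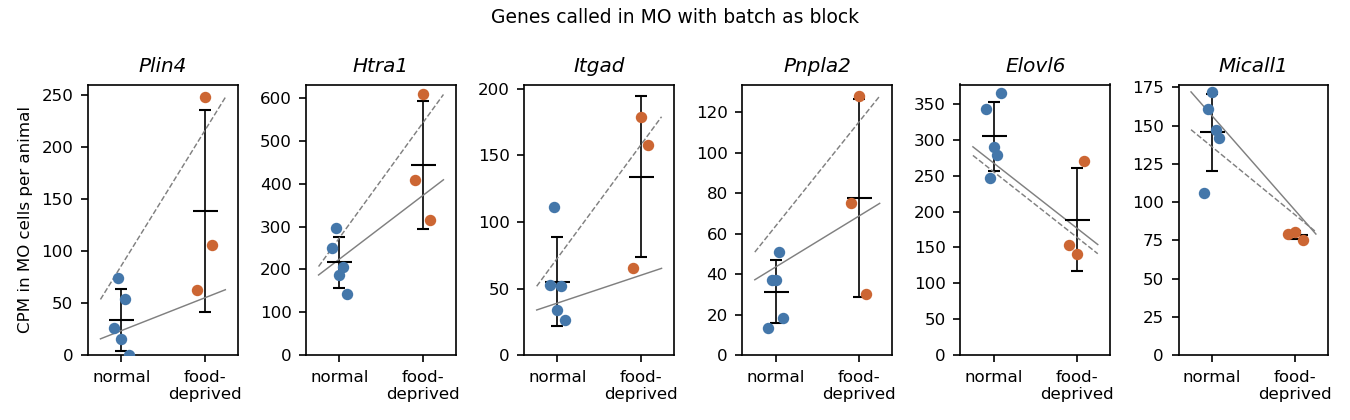
Points are mice, normal at the left and food-deprived at the right of each panel, in CPM of summed MO cells; short bars are means and whiskers the SD, and the grey lines join the mice of batch 1 (solid) and batch 2 (dashed). In both shared batches the food-deprived mouse is higher for Plin4, Htra1, Itgad and Pnpla2 and lower for Elovl6 and Micall1.

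In OPC, Hspa5, the chaperone of the endoplasmic reticulum, stood at 1064 ± 199 CPM in 4 normal and 542.7 ± 133 CPM in 3 food-deprived mice. All 3 food-deprived mice were below all 4 normal ones. With batch as block Hspa5 was lower (-1.23 ± 0.16 SE, adjusted p = 4.05e-10). Only the mice of batches 1 and 2 inform the blocked values, and their p rest on a spread pooled largely over genes. Hsp90b1 (-0.86 ± 0.16, adjusted p = 8.25e-05) and Hsph1 (-0.82 ± 0.19, adjusted p = 0.00762) fell too. Avp rose by 1.89 (adjusted p = 6.93e-07), a peptide gene whose highest level lies in Glu14 neurons. Its level was highest in food-deprived replicate 1, at 147.8 CPM. Normal replicate 5 (59.9 CPM) lay above food-deprived replicates 2 (47.8 CPM) and 3 (34.3 CPM). Hes5 was called lower (-1.33, adjusted p = 2.32e-05), but it stood at -0.56 without the block and was highest of the 7 mice in food-deprived replicate 3, at 274.8 CPM. Of the 18 OPC calls 7 were genes of the library types, Rbm3, Ppia, Rps23, Gapdh, Rps27a and the blood gene Beta-s, higher, and Oxt, lower. Without the block Hspa5 stood at -1.03 ± 0.20 and Hsp90b1 at -0.61 ± 0.18, with adjusted p of 0.248 and 1. In depleted libraries alone Hspa5 and Hsp90b1 kept their calls, at adjusted p of 5.35e-12 and 3.49e-08. In retained libraries alone, tested without the block, 0 genes passed in OPC, and Hspa5 and Hsp90b1 stood at -0.86 and -0.56. In Tany, Cdkn1c (-2.08 ± 0.42, adjusted p = 0.00495), Slc13a3, Col27a1, Scn7a and 1500015O10Rik fell and Penk (1.56 ± 0.36, adjusted p = 0.0261) and Hist1h1c rose, but with 0 calls in edgeR over batches 1 and 2 alone, where 264 genes had an unadjusted p under 0.05. In all neurons Pvalb, Ghrh, Vip, Prph, Pomc, Gapdh and Ppia were higher and Tac2 lower, and in depleted libraries alone Vip, Gapdh and Ppia lost their call (adjusted p of 0.599, 0.979 and 0.974). Tac2, Ghrh and Pomc are peptides of Glu11, GABA11 and Glu13, whose share of the neurons also differed between the mice of at least 1 batch, so these values mix cluster share and level per cell. In Glu, Pomc and Cldn11 were higher and Tac2 lower, and in IMO H2-K1 was higher. The block gave no call in GABA, Astro, Ependy, Epith and Micro, where 538, 373, 353, 329 and 210 genes had an unadjusted p under 0.05, and with DESeq2 and the block none of these 5 classes had a call either. DESeq2 with the block also gave 0 calls in OPC, Tany and IMO, where 5, 14 and 6 genes had an unadjusted p under 0.05, so the OPC, Tany and IMO calls rest on edgeR alone, and it gave 3 in MO, 2 in all neurons and 1 in Glu. Exchanging the status of the batch 1 mice, which leaves the block fit but breaks the grouping, gave 1 call in MO against 16, and 15 in OPC against 18, 4 in Tany against 7, 3 in all neurons against 8, 2 in Glu against 3 and 1 in IMO against 1, with 5 in GABA and 1 in Ependy where the real status gave 0.

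Gene lists moved in 54 of 209 list and class pairs in camera, 29 up and 25 down. Heat shock genes were lower in 8 of 11 classes and unfolded protein response genes in 7 of 11. Among the 8 are all neurons, GABA and Glu, which share cells. None of the 54 held with an estimated correlation, where the smallest adjusted p was 0.313, and fry passed none (smallest 0.214). Over all 56 splits of the mice into groups of these sizes, camera passed a median of 43.5 pairs. With batch as block 70 pairs passed, against 45 with the status exchanged in batch 1, and without normal replicate 4 46 did. In scores per mouse, the groups were fully separated in 16 of the 54 pairs (29.6%) and in 21 of all 209 (10.05%), where chance gives 9.47%.

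In OPC all 13 heat shock genes past the filter were lower in the food-deprived mice (median log2 fold change -0.42, adjusted p = 1.02e-07; adjusted p = 0.313 with an estimated correlation), led by Dnajb1 (129.4 ± 57.5 to 79.2 ± 26.2 CPM) and Hsph1 (263.8 ± 80.2 to 176.9 ± 45.2 CPM). The score fell from 8.20 ± 0.15 (n = 4) to 7.82 ± 0.04 (n = 3), with all food-deprived mice below all normal ones (exact permutation p = 0.0286, the smallest that 35 splits can give). Unfolded protein response genes were lower in OPC for 19 of 22 members (median -0.24, adjusted p = 1.88e-07; 0.344 with an estimated correlation), among them Manf (195.2 ± 32.4 to 120.4 ± 15.2 CPM) and Sdf2l1. Adjusted over the list alone, 3 members were lower and 0 higher in OPC. Immediate early genes did not move with them in OPC (median -0.06). In Ependy heat shock genes were lower for 14 of 15 members (median -0.999, adjusted p = 3.89e-11; 0.502 with an estimated correlation), 8 of them adjusted over the list alone, with Dnajb1 at 674 ± 610 and 120.7 ± 44.7 CPM (n = 3 each). Unfolded protein response genes were lower there for 14 of 17 members (adjusted p = 8.02e-07; 0.535), with Hsp90b1 at 2215 ± 372 and 1049 ± 207 CPM. The unfolded protein response list was also lower in Tany (adjusted p = 9.36e-05; 0.502), with Hspa5 at 1003 ± 101 and 652.4 ± 171 CPM and Creld2 at 153.3 ± 31.3 and 95.6 ± 4.74 CPM, and in Epith (adjusted p = 0.00136; 0.535). Heat shock genes were lower in MO (adjusted p = 9.41e-05; 0.344) and IMO (adjusted p = 0.00136; 0.502). The preset calls of these pairs survived the loss of any 1 mouse, in IMO with 1 food-deprived mouse left after the loss of another. In GABA, Epith and all neurons heat shock genes were lower at adjusted p of 9.12e-06, 3.83e-05 and 4.56e-05 (0.502 each with an estimated correlation), and the call ended in GABA in depleted libraries alone (0.285), in Epith in retained ones (0.151) and in all neurons with the block (0.0515). In Glu (0.0335; 0.605) the heat shock call ended without food-deprived replicate 1 (0.309), normal replicate 4 (0.111) or normal replicate 5 (0.315). The unfolded protein response call in IMO (0.0074; 0.502) ended without food-deprived replicate 2 (0.0579) or normal replicate 3 (0.0783), in MO (0.0231; 0.574) without food-deprived replicate 2 (0.282) or normal replicates 1 (0.0658) or 3 (0.139), and in Micro (0.0193; 0.605) without food-deprived replicates 1 (0.18) or 2 (0.0673) or normal replicate 4 (0.23).

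**Figure D4:**
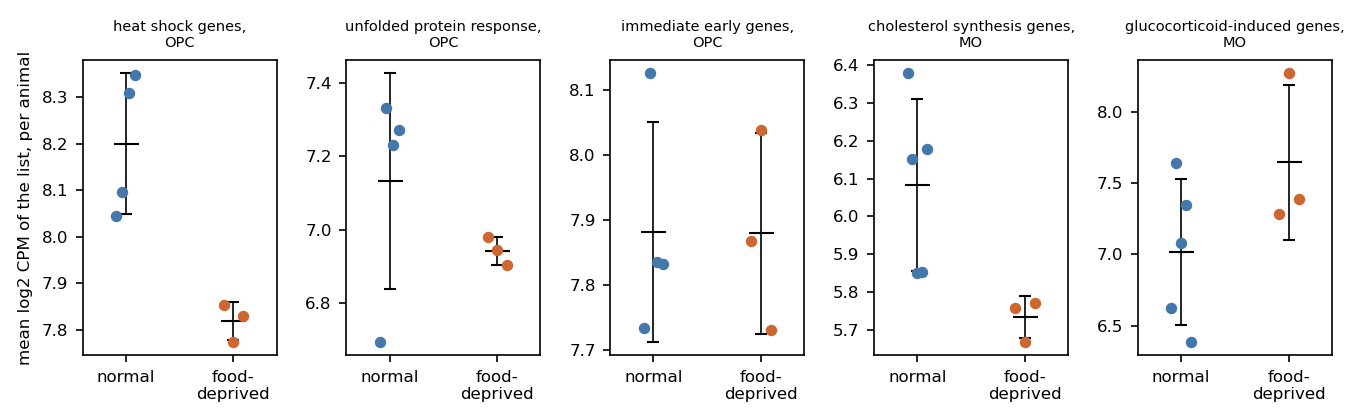
Points are mice, normal at the left and food-deprived at the right, and the vertical axis is the mean log2 CPM of the named list in the named class; short bars are means and whiskers the SD. Heat shock scores in OPC and cholesterol synthesis scores in MO are separated between the groups, and immediate early gene scores in OPC overlap.

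In MO glucocorticoid-induced genes were higher for 18 of 20 members (median log2 0.51, adjusted p = 7.01e-08; 0.574 with an estimated correlation), 7 of them adjusted over the list alone, and no single mouse ended this call. Mt1 rose from 1781 ± 400.5 CPM (n = 5) to 3060 ± 592 CPM (n = 3) among these 7, beside Plin4, Phyhd1 and Fam107a. Phyhd1 was highest in normal replicate 2 (74.2 CPM) and stood at 29.3, 45.2 and 0 CPM in food-deprived replicates 1 to 3. Fam107a stood at 49.5 CPM in normal replicate 2, with the nearest normal mouse at 13.8 CPM. Cholesterol synthesis genes were lower in MO for 20 of 23 members (adjusted p = 9.47e-05; 0.574), with a score of 6.08 ± 0.23 against 5.73 ± 0.06 (exact permutation p = 0.0357) and Fdft1 at 170.3 ± 48.2 against 88 ± 17.7 CPM, and the call ended in depleted libraries alone (0.0674). Fatty acid synthesis genes were lower in MO (adjusted p = 0.0226; 0.502; without food-deprived replicate 3 0.0509), Ugt8a standing at 1361 ± 362 and 892.6 ± 179 CPM. Cholesterol synthesis genes were lower in Astro (adjusted p = 8.01e-05; 0.502; 0.685 in retained libraries alone), with Cyp51 at 145.3 ± 33.5 and 80.1 ± 5.62 CPM (n = 3 each), and in IMO (0.00327; 0.628), where the call ended with the block (0.0519), without food-deprived replicate 2 (0.446) or without normal replicate 3 (0.122). Tany showed lower fatty acid synthesis genes (0.0209; 0.502), Acss2 standing at 71.2 ± 12.5 and 35 ± 4.83 CPM, and this ended with the block (0.142) and without food-deprived replicate 3 (0.0797) or normal replicate 4 (0.0711). Feeding peptides were higher in MO (0.0391; 0.502), led by Pomc at 3.88 ± 3.63 and 62.1 ± 64.4 CPM. Glucocorticoid-induced genes were also higher in Glu (4.37e-05; 0.502; 0.142 in retained libraries), with Glul at 47.5 ± 13.8 and 96.4 ± 4.93 CPM and Mt1 at 181.5 ± 56.1 and 322.2 ± 46.4 CPM (n = 3 each). In all neurons they passed at 0.0231 (0.502) with Tsc22d3 at 50.5 ± 6.68 and 70.9 ± 6.52 CPM, and the call ended without food-deprived replicate 2 (0.131), normal replicate 3 (0.223) or normal replicate 5 (0.0612), in retained libraries alone (0.526) and without the neurons rich in myelin RNA described below (0.0677). They passed at 0.0199 in Astro and in IMO (0.693 and 0.577 with an estimated correlation), both calls ending with the block (0.0553 and 0.139) and without food-deprived replicate 2 (0.82 and 0.109) or normal replicate 5 (0.627 and 0.0775), in Astro also without normal replicate 4 (0.158) and in IMO also without normal replicate 3 (0.0513).

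Immediate early genes were lower in all neurons for 28 of 30 members (median log2 -0.34, adjusted p = 7.27e-06; 0.502 with an estimated correlation), among them Nr4a2 (21 ± 16.2 to 9.25 ± 5.1 CPM) and Klf4 (65.7 ± 15.4 to 39.2 ± 12.3 CPM; n = 4 and 3), and no single mouse ended the call. In GABA they were lower as well (2.49e-05; 0.492; 0.0641 in depleted libraries alone). In Astro they were lower (9.41e-06; 0.628), which ended and turned without normal replicate 3 (0.83). In Tany (6.36e-05; 0.574), MO (0.000261; 0.535) and Micro (0.000553; 0.574) they were higher. Without food-deprived replicate 2 the calls in Tany (0.109) and MO (0.364) ended, and without normal replicate 4 the call in Micro (0.212). Microglial activation genes were higher in Micro for 17 of 21 members (median 0.25, adjusted p = 9.12e-06; 0.492), with Ccl4 at 6202 ± 923 CPM (n = 3) against 13640 ± 1972 CPM (n = 2), Ccl3 at 3531 ± 622 against 7562 ± 1122 CPM and Il1b at 550.8 ± 197 against 1145 ± 14.8 CPM. Adjusted over the list alone, 2 members of it were higher.

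Myelin genes were higher in food-deprived Glu cells for all 13 members (median log2 0.90, adjusted p = 1.8e-12; 0.535 with an estimated correlation), 4 of them adjusted over the list alone. Mal stood at 16.7 ± 4.04 and 47 ± 10.5 CPM and Cldn11 at 11.1 ± 4.85 and 53.5 ± 32 CPM (n = 3 each). In all neurons the list passed at 7.97e-08 (0.574). Both calls ended in retained libraries alone (0.18 in Glu and 0.178 in all neurons). They also ended when neurons with at least 1% of their UMIs from the list were left out (0.431 in Glu and 0.434 in all neurons), an alternative chosen after seeing the data. These 23 neurons had a median of 1169 UMIs against 3940 in the other neurons. The list was higher in Micro (7.27e-06; 0.628; 0.761 without normal replicate 4, 0.77 in depleted libraries alone) and lower in Tany (0.00614; 0.628), where the direction turned with the block (0.0883) and the call ended without food-deprived replicate 3 (0.874) or normal replicate 5 (0.486). In Tany, 2 cells of normal replicate 5, both called doublets, held 1016 of its 1187 myelin UMIs. Micro cells with at least 1% of UMIs from the list held 2698 of 4045 and 2051 of 2972 myelin UMIs in food-deprived replicates 1 and 2. In normal replicate 3 they held 2824 of 3772. The other Micro cells had 32.4 and 30.8 per 10000 in these food-deprived mice, and 34.8, 33 and 20.7 in normal replicates 3 to 5. The list was not retested without such cells in either class.

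**Figure D5:**
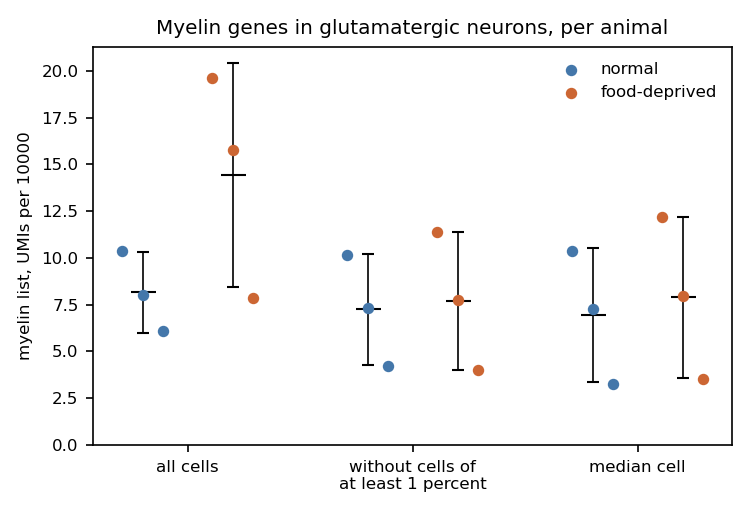
Points are mice (3 normal, 3 food-deprived), and the vertical axis is UMIs of the myelin list per 10000 UMIs of glutamatergic neurons, with means as short bars and SD as whiskers. Over all cells the means are 8.16 and 14.4, and for the median cell 6.97 and 7.89.

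Other lists passed in some classes with calls that single mice carried. Ribosomal protein genes, which differ between the library types, were higher in Astro (7.35e-08; 0.628 with an estimated correlation), Micro (1.06e-05; 0.704), Glu (0.00136; 0.771) and OPC (0.0142; 0.76, with a median of -0.14, opposite to the test). Leaving out normal replicate 3 ended the Astro call (0.143) and turned the direction in Micro (0.00154), Glu (0.00605) and OPC (0.00162). Without the genes that differ between library types the calls in Astro (0.424) and OPC (0.354) ended, as they did in depleted libraries alone (0.439 and 0.249). The Astro call also ended without normal replicate 4 (0.0616), as did the OPC call (0.457), the Micro call ended without food-deprived replicate 2 (0.625), and the Glu and OPC calls ended without food-deprived replicate 3 (0.51 and 0.41). Oxidative phosphorylation genes were higher in all neurons (0.000862), MO (0.00136), Glu (0.0021), OPC (0.00863) and GABA (0.0151), with 0.502 to 0.711 at an estimated correlation. Without normal replicate 4 all but the MO call ended (0.365, 0.81, 0.68 and 0.554 in all neurons, Glu, OPC and GABA), and without food-deprived replicate 1 those in MO (0.0778), OPC (0.175) and GABA (0.418), the last also without food-deprived replicate 2 (0.109). The MO call also ended in retained libraries alone (0.0719), and the OPC call in depleted ones (0.105). Glycolysis genes were higher in MO (0.00673), Tany (0.00812) and Glu (0.0145), with 0.574 to 0.605 at an estimated correlation. Food-deprived replicate 1 carried the calls in MO (0.124 without it) and Tany (0.119), normal replicate 5 that in Tany (0.17), food-deprived replicate 2 that in Glu (0.1), and normal replicate 4 those in MO (0.0629) and Glu (0.282). Peptide processing genes were higher in Tany (0.00812; 0.574; 0.137 without food-deprived replicate 1), with Scg2 at 45.1 ± 17.2 and 178.5 ± 140 CPM, and in MO (0.0353; 0.577), which ended without food-deprived replicate 1 (0.187) or normal replicates 1 (0.0975) or 4 (0.158). Fatty acid oxidation and ketone genes were higher in Epith (0.0142; 0.574; 0.178 without food-deprived replicate 2, 0.0711 without normal replicate 4, 0.812 in retained libraries alone), with Angptl4 at 30.6 ± 10.6 and 81.8 ± 49.9 CPM. Interferon-induced genes were lower in Ependy (0.0411; 0.574), which ended without food-deprived replicate 1 (0.126) or normal replicates 3 (0.125) or 4 (0.229). Circadian clock genes were higher in Glu (0.0476; 0.631), which ended with the block (0.411) and without food-deprived replicate 2 (0.74) or normal replicates 4 (0.0643) or 5 (0.712). That call also ended in depleted libraries alone (0.861) and without the neurons rich in myelin RNA (0.0518).

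Orexigenic peptides (4 classes), anorexigenic peptides (6), hypothalamic peptides (8), transmitter genes (4), FoxO and low-insulin genes (11), thyroid hormone handling (7), mural and fibroblast genes (1) and genes of extrahypothalamic neurons (1) did not pass in the classes tested, with smallest adjusted p of 0.235, 0.0887, 0.0541, 0.111, 0.093, 0.168, 0.288 and 0.673. Genes of blood, pituitary, choroid plexus and sex had under 5 members past the filter in every class, and the tables hold no mitochondrial-encoded transcript.

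Glutamatergic and GABAergic neurons were compared in their responses. Hcrt, a peptide of glutamatergic Glu12 cells, had the smallest p, with log2 ratios of 4.39 in Glu and -0.06 in GABA (difference 4.61 ± 0.95 SE, adjusted p = 0.675). Kiss1 differed by -1.80 ± 0.43, Synpr by -1.07 ± 0.22 and Gm13889 by 1.37 ± 0.33. Ninl, 2010001M06Rik, Usp51, Asb4 and Rundc3b were also among the 10 genes with the smallest p. None of 10012 genes passed in edgeR, 360 had an unadjusted p under 0.05, and no other tool was run. Leaving out normal replicate 5 gave 3 calls, Hcrt (adjusted p = 1.86e-05) and Kiss1 (0.00104) among them, and leaving out food-deprived replicate 1 or 3 gave 1 each. With a batch by class term there were 25 calls, Hcrt (1.57e-20) and Kiss1 (7.62e-28) among them. Food-deprived replicate 2 carries Hcrt, with 4651 CPM in Glu against 156.3 and 89.9 CPM in food-deprived replicates 1 and 3, and without it the adjusted p of Hcrt and of Kiss1 is 1.

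Single neuronal clusters were compared where mice had at least 10 cells. GABA13, the Gal cluster, showed 148 genes at an unadjusted p under 0.05 over 91 normal and 73 food-deprived cells (3 mice each), and GABA8, the Avp cluster, 110 genes over 172 and 227 cells (4 and 3 mice). Counts were 61 in GABA15, 253 in Glu4, 112 in Glu5 and 87 in Glu7. None of the 6 clusters had a gene past the threshold in edgeR, the tool run here, and the smallest adjusted p was 0.0641, in Glu4. Without normal replicate 3, GABA13 had 2 calls, Gal (1.60 ± 0.21, adjusted p = 0.0125) and Sparcl1 (3.18 ± 0.50, adjusted p = 0.0399), both higher. With batch as block 2 of the 3 clusters that could be fitted had calls. GABA8 had 22, of which Vip (4.24) and Hspa1a (3.05) are outside the genes of the library types, and Glu4 had 7, with the myelin genes Mal, Mog and Car2 higher. In Glu4, 2 cells held 657 of the 897 myelin UMIs of food-deprived replicate 1 and 1 cell 1077 of the 1286 of food-deprived replicate 2, and without them these mice had 11 and 6.61 myelin UMIs per 10000, against 9.28 and 10.7 in normal replicates 3 and 4.

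In GABA15, the cluster richest in Agrp, Agrp stood at 4908 ± 2644 CPM in normal replicates 2, 3 and 5 and at 6677 and 7104 CPM in food-deprived replicates 1 and 3 (log2 0.48 ± 0.42 SE). Npy stood at 11380 ± 3769 CPM against 15280 and 14950 CPM (0.40 ± 0.32), and Pomc at 36.5 ± 23 CPM against 102.7 and 85.2 CPM (1.32 ± 0.66). Sst (0.54), Npy2r (0.22), Scg2 (0.16), Cartpt (0.02), Acvr1c (-0.03), Serpina3n (-0.07) and Vgf (-0.66) complete the 10 list members tested. Lepr, Ghsr, Insr, Npy1r, Gal, Pnoc, Corin, Otp and Ghrh were under the filter. None of the 10 passed in edgeR adjusted over the list alone (smallest adjusted p = 0.687) or over all 2898 genes, of which 42 had an unadjusted p under 0.05. Without normal replicate 2, 4 members had an unadjusted p under 0.05 and the smallest adjusted p over the list alone was 0.071, against 0 members with all 5 mice. These values rest on 15, 6 and 38 normal and 27 and 20 food-deprived cells.

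Astro made up 5.46% ± 2.52 of the annotated cells in the normal mice (n = 5) and 9.45% ± 1.64 in the food-deprived mice (n = 3), the smallest p among 16 classes (two-sided exact permutation p = 0.107, adjusted p = 1). Within batches 1 and 2 the difference was -1.26 and 5.55 points. IMO made up 2.40% ± 1.91 and 0.78% ± 0.37 (p = 0.161, exact), MO 24% ± 4.09 and 21.4% ± 14.4, neurons 18% ± 6.47 and 17.9% ± 7.29, OPC 13.5% ± 5.65 and 10.6% ± 3.46, and Tany 6.38% ± 4.07 and 6.98% ± 8.32. Without the batch 0 mice IMO stood at 1.13% and 0.78%. Food-deprived replicate 3 had 4.74% of MO and 16.6% of Tany, and without it the food-deprived means were 29.7% and 2.18%. Within batches 1 and 2 the difference was 4.73 and 3.91 points in MO and -1.525 and 1.01 points in Tany. No share passed the permutation test after adjustment over the 16 classes. The smallest unadjusted p that 56 splits can give is 0.0179. A lone class at that p could not pass the adjusted threshold unless several other classes reached it too. The adjusted test therefore could not decide whether the share of any single class changed.

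In the sum of all annotated cells Plin4 was higher with batch as block (2.08 ± 0.23 SE, adjusted p = 0.00474), as were Pomc, Vip, Ccl4 and Itgad, and Cga was lower (-4.74 ± 0.34, adjusted p = 0.000124). Without the block Cga stood at 0.47 ± 1.67, since it was high in normal replicates 3 and 5 and in food-deprived replicate 3 (188.3, 129.1 and 307.5 CPM). The blocked value rests on batch 1, with 188.3 CPM in normal replicate 3 and 6.72 CPM in food-deprived replicate 1, since the batch 2 mice had 0 and 0.101 CPM. Without the block no gene of 14143 passed in edgeR, where 117 had an unadjusted p under 0.05, and DESeq2 called 0. With the block 20 passed, 10 in each direction, against 3 with the status exchanged in batch 1.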

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

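All tests of explanations in this part, and the alternatives by library type and without neurons rich in myelin RNA, were chosen after the results were seen.

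Myelin genes were higher in food-deprived Glu neurons for all 13 members, and the tables argue for a small number of cells behind it. Leaving out neurons with at least 1% of their UMIs from the myelin list raised the adjusted p from 1.8e-12 (0.535 with an estimated correlation and 0.661 in fry) to 0.431. Over the 11 members tested both ways, the median log2 fold change went from 0.88 (SD 0.55 over members) to 0.05 (SD 0.33), so the fold itself shrank, while 9 of the 11 were still higher. Of the Glu neurons left out 5 were from each group, and they held 1017, 1077 and 217 myelin UMIs in the food-deprived mice and 20, 41 and 146 in the normal mice. Over all neurons 23 were left out, 16 from food-deprived mice, of which 14 were from food-deprived replicate 1, and Scrublet called 7 of the 23 (30.4%) doublets against 0.924% of the other neurons, which is consistent with oligodendrocyte RNA in a few neurons. Free RNA spread over all cells would raise the other neurons too, and their median of 0.0478 lay below 0.88 by more than the SD over members. This test replaced an earlier one, on the median neuron, after the values of both were seen. The earlier one could not tell, since the median Glu neuron held 7.89 ± 4.32 myelin UMIs per 10000 in the food-deprived mice and 6.97 ± 3.59 in the normal mice (SD, n = 3 each). The new one leaves out neurons by their myelin UMIs in both groups, which by itself lowers the fold, so it cannot decide on free RNA either. The other Glu neurons held 11.4, 7.73 and 4.02 myelin UMIs per 10000 in the food-deprived mice and 10.2, 7.33 and 4.25 in the normal mice.

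Heat shock and unfolded protein response genes were lower in food-deprived OPC, among them Hspa5, Hsp90b1, Manf and Dnajb1, but neither list passed with an estimated correlation (0.313 and 0.344) or in fry (0.214 each). The type of library as the whole cause is argued against by depleted libraries alone, where both lists stayed lower with adjusted p of 1.02e-08 or less. Less stress during dissociation of the food-deprived tissue could lower chaperone genes, and the immediate early genes in OPC do not decide it: their median log2 fold change was -0.0639 (SD 0.26 over 27 members), against -0.42 (SD 0.21) for heat shock and -0.24 (SD 0.35) for the unfolded protein response. Exchanging the status of the batch 1 mice left 15 calls in OPC under the block against 18, so the single genes called there are no firmer than that count. Heat shock genes were lower in 8 of 11 classes and unfolded protein response genes in 7 of 11, so the fall was not particular to OPC. The 8 include all neurons, GABA and Glu, which share cells. Immediate early genes were lower in all neurons, GABA and Astro and higher in Tany, MO and Micro. A response of OPC to food deprivation remains among the open explanations, untested.

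Plin4, Htra1, Pnpla2, Elovl6 and 12 other genes were called in MO with batch as block. Of the 14 that are not genes of the library types, 12 kept their call in depleted libraries alone, which argues against the library type for these, while of Ppia and Gapdh 0 kept it, which fits the library type for this pair. RNA of another named class is argued against for 3 of the 11 genes called higher, Plin4, Itgad and Gm15417, whose level in MO of each food-deprived mouse lay above the mean plus SD of each of 12 other classes, or above the level alone where a class was too small for an SD. SCO and the 2309 unnamed cells were not compared, so RNA from them is not covered. Their lowest food-deprived levels in MO were 62.9, 65.4 and 73.8 CPM, and the highest means elsewhere 27.6 ± 21.7 CPM in Ependy, 23.2 ± 32.9 CPM in Macro and 43.6 ± 29 CPM in Astro. For the remaining 8, such as Pomc with 1884 CPM in Glu and Scrg1 with 1273 CPM in OPC, RNA of another class may contribute and cannot be told apart from a change in MO, since their lowest food-deprived MO level is not above that bound. Gabrr2 is among these 8: its lowest level of 14.8 CPM lay above every mean, but within the SD of Macro (13.9 ± 19.7 CPM), and the SD was added to this test after these values were seen. The 3 genes called lower, Elovl6, Micall1 and Eml1, were not covered by that test, and an effect of food deprivation on MO stays open as a hypothesis.

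Other splits of the mice were counted for each result across genes. For the gene lists, the 56 splits passed a median of 43.5 pairs. As many as the 54 of the real split passed in 11 of the 56, with 72 in normal replicate 3 and food-deprived replicates 1 and 2 against the rest, so chance cannot be excluded for that count. These 3 mice hold 8 of the 9 depleted libraries, and with batch as block 70 pairs passed, against 45 with the status exchanged in batch 1. For single genes the real count was 0 in edgeR, so that every split is as large by construction and the count of splits decides nothing: 56 of 56 for all cells summed (highest other 1651) and for MO (33), and 35 of 35 for all neurons (187), GABA (140), OPC (82) and GABA8 (62). Except in MO, these highest counts came from normal replicates 2 and 5 with food-deprived replicate 3, mice whose libraries are all of the retained type, which points to a structure of the samples. In Glu, Astro, Tany, Ependy, Epith, GABA13 and the Glu and GABA difference, 10 splits are too few for a share under 0.05, with 0 in the real split and at most 14, 5, 39, 56, 29, 15 and 17 in another.

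In 13 of 150 groups of 4 or 5 normal mice, 1 mouse stood far from the others. Chance gives about 1 in 20 for normally distributed values of equal precision, which CPM of mice of such unequal depth are not. In all neurons normal replicate 2 had Agrp at 4448 CPM (nearest 209.1), Npy at 8578 CPM (1068), Vgf at 1309 CPM (397.1) and Tsc22d3 at 40.5 CPM (53.7). Normal replicate 5 had Pomc at 974.7 CPM (106.7) and Prph at 37.6 CPM (8.49), normal replicate 4 had Sst at 2563 CPM (755.1), and normal replicate 3 had Pmch at 253.5 CPM (42). In MO normal replicate 2 had Phyhd1 at 74.2 CPM (4.31) and Fam107a at 49.5 CPM (13.8), and normal replicate 1 had Sdf2l1 at 13.2 CPM (39.6). Normal replicates 1 and 2 held 37 and 36 MO cells, and normal replicate 2 held 41 neurons. Low CPM values there, Tsc22d3 included, rest on few UMIs. The percentage of Hista cells was 0.322 in normal replicate 5 (nearest 0.039) and that of SCO cells 1.25 in normal replicate 3 (nearest 0).

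Barcodes without a cluster name, which no comparison used, held 903323 UMIs in the food-deprived and 1102120 in the normal mice. Avp stood there at 559 CPM in the food-deprived and 377.5 CPM in the normal mice, Oxt at 517 and 342.1 CPM, and Plin4 at 17.7 and 2.72 CPM, sums over mice that were not tested.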

How the results depend on the processing

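Alternatives that use the library types, the block with RLE factors or DESeq2, and leaving out neurons rich in myelin RNA were chosen after seeing the data. The cause of a changed count was not tested unless given.

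Counts of genes in the 11 classes, 0 with status alone, changed as follows. DESeq2 gave 1, in MO. Without a filter 129 passed: 5 in GABA, 37 in Glu, 22 in MO, 1 in IMO, 3 in OPC, 18 in Astro, 14 in Tany, 21 in Ependy, 5 in Epith and 3 in Micro. Adding batch as block let 53 pass: 8 in all neurons, 3 in Glu, 16 in MO, 1 in IMO, 18 in OPC and 7 in Tany, with 20 in all cells summed. Without the genes of the library types the block gave 67: 13 in all neurons, 1 in GABA, 11 in Glu, 22 in MO, 2 in IMO, 10 in OPC, 7 in Tany and 1 in Epith, with 44 in all cells summed. Batches 1 and 2 alone gave 141: 14 in all neurons, 1 in GABA, 7 in Glu, 71 in MO, 2 in IMO, 17 in OPC and 29 in Astro. The block with RLE gave 60: 10 in all neurons, 9 in Glu, 15 in MO, 1 in IMO, 18 in OPC and 7 in Tany. With DESeq2 it gave 6: 2 in all neurons, 1 in Glu and 3 in MO. Depleted libraries alone, over batches 1 and 2 and with the block, so that 3 choices change at once, gave 129: 14 in all neurons, 22 in GABA, 22 in Glu, 37 in MO, 15 in OPC, 8 in Astro and 11 in Epith. Leaving out 1 mouse gave 0 to 12 over all classes (12 without normal replicate 3, 4 without food-deprived replicate 1 or 2), with 0 to 12 in Micro (normal replicate 3), 0 to 3 in IMO (food-deprived replicates 1 and 2), 0 to 1 in MO (food-deprived replicate 1) and 0 to 1 in Tany (food-deprived replicate 2), where IMO and Micro keep a lone food-deprived mouse if 1 of their 2 is left out.

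For the Glu and GABA difference, 26 genes passed without a filter, 25 with a batch by class term, and 0 to 3 without 1 mouse (3 without normal replicate 5, 1 without food-deprived replicate 1 or 3). Clusters with a call numbered 2 with batch as block, 1 with a minimum of 20 cells, and 0 to 1 without 1 mouse (normal replicate 3). For gene lists, 0 pairs passed with an estimated correlation and 0 with fry, 31 in retained libraries alone, and 46 to 70 without 1 mouse.

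Genes whose direction turned are mostly genes of the library types. Under the block Gapdh turned to 2.10 in all neurons and 1.79 in MO, Ppia to 1.13 in all neurons, 1.35 in MO, 1.00 in OPC and 1.21 in all cells summed, Rps23 to 1.11 and Rps27a to 0.86 in OPC, and Cga in all cells to -4.74 (-4.73 without the genes of the library types). Over batches 1 and 2 Gapdh stood at 2.09 in all neurons and 1.79 in MO, Ppia at 1.13, 1.33 and 1.00 in all neurons, MO and OPC, and Rps23 at 1.13 in OPC. With RLE and the block Gapdh stood at 2.09 in all neurons, Ppia at 1.13, 1.35 and 1.00 in the same 3 classes, and Rps23 and Rps27a at 1.12 and 0.86 in OPC. With DESeq2 and the block Gapdh stood at 2.24 in all neurons and Ppia at 1.37 in MO. In depleted libraries alone Oxt turned to 3.24 in all neurons. The list of myelin genes in Tany turned with the block (0.0883) and over batches 1 and 2 (0.0851). Without 1 mouse the adjusted p ran from 4.8e-29 to 0.51 for ribosomal protein genes in Glu, 7.3e-16 to 0.625 in Micro and 2.67e-15 to 0.457 in OPC, turning without normal replicate 3 (0.00605, 0.00154 and 0.00162), and from 1.3e-13 to 0.83 for immediate early genes in Astro, turning without normal replicate 3 (0.83).

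No gene passed the threshold in the main tests, so an unchanged call of a gene means no call. Over all alternatives, gene values numbered 5250 with an unchanged call, 323 newly past the threshold, 185 of another sign with no call and 25 reversed with a call. List pairs numbered 721 kept, 209 no longer past the threshold and 6 reversed. Cell shares, of which none passed the threshold, numbered 159 with the same sign and 32 with another sign or 0. GABA15 with batch as block was not run, since 5 mice leave no residual degrees of freedom. Depth limits the batch 0 mice, whose totals are 290861 and 390595 UMIs. Simulated 2-fold changes, placed in genes at or above the median CPM, were recovered for 12% of genes in Astro and 14% in Micro, the lowest of the 11 classes.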

Other observations

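The tests in this part were chosen after the data were seen, and the cluster levels follow the rule for naming genes.

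Further clusters carried peptide genes that the report does not describe. GABA16 held Cartpt at 4098 ± 1295 CPM (SD, n = 5 mice), Glu8 Cartpt at 2072 ± 1120 CPM (n = 5) and Glu6 Tac1 at 2067 ± 1144 CPM (n = 6). GABA5 held Sst at 4886 ± 6776 CPM and Npy at 3081 ± 3635 CPM (n = 4), an SD above the mean for both. In Glu1, where 2 mice had at least 5 cells, Crh stood at 1423 and 4127 CPM beside Avp at 1290 and 29720 CPM, and Trh led at 2047 CPM in Glu10, where 1 mouse did. Nms stood at 616 ± 289.9 CPM in GABA8 (n = 7), beside Avp, and Grp at 974 ± 817 CPM in GABA9 (n = 6), beside Vip. Penk stood at 1968 ± 528 CPM in GABA17 (n = 5), beside Cartpt. Hdc reached 558 ± 88.3 CPM in Ependy (n = 8).

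Batch mates were compared by Pearson's r of their deviations from the group mean over genes within a class, over the 3 normal and 3 food-deprived mice of batches 1 to 4. Genes are not independent samples, and deviations from a mean of 3 mice constrain each other. In all neurons r was 0.579 for the batch 1 mice and 0.075 for the batch 2 mice, in MO 0.339 and 0.168, and in OPC 0.193 and 0.092. Normal replicate 3 and food-deprived replicate 2, of different batches, had 0.239 in all neurons, 0.112 in OPC, 0.130 in Epith and 0.065 in Tany, above the batch 2 mates. In MO (0.159) and Astro (0.044) this pair was below the batch 2 mates, at 0.168 and 0.184. Normal replicate 5 and food-deprived replicate 3, which are from different batches and have retained libraries only, had 0.624 in all neurons and 0.299 in MO.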
